A study of Arabidopsis thaliana with 24 samples.

How the data were processed

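The data were transcript counts from 24 libraries of Arabidopsis thaliana seedlings, 12 from roots and 12 from shoots, in 8 groups of 3 biological replicates. Seedlings of the wild type Columbia-0 were 7 days old, and each replicate pooled 30 to 50 of them, per the labels' protocols. They were held in 30% (w/v) polyethylene glycol (PEG) of average molecular weight 8000, at -2.0 MPa, for 1, 2 or 3 h, or in water for 1 h, and roots and shoots were parted after the treatment, per the labels' protocols. Libraries were made by MARS-seq, a method that counts transcripts from their 3′ ends, and sequenced on a NextSeq 500, per the labels' protocols. Whether reads with the same molecular identifier were collapsed is not given in the sources used here.

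Reads were converted with bcl2fastq, trimmed with cutadapt, aligned with STAR version 2.4.2a, counted per gene with HTSeq and tested with DESeq2, per the submitters' processing notes. The authors deposited 1 table of 18240 genes with counts per gene and library, per the file headers. A further set of values per library holds the authors' normalized signal, which was checked to equal the counts divided by 1 size factor per library, with a largest relative spread of 9.8e-15. Those deposited size factors matched size factors recomputed with DESeq2 to a relative gap of 6.7e-16. Another set holds the authors' log2 values per library after a regularized logarithm, per the file headers. The authors also deposited a log2 fold change, a p-value and an adjusted p-value for each of their contrasts, per the file headers. Every gene listed had at least 6 counts in some library. No genome build was named, so no positions are given. Gene symbols came from the RefSeq table of assembly TAIR10.1, in which 18125 of the 18240 identifiers were found and 115 were not. All columns that belong to a library were mapped to a group.

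Only the deposited counts entered the tests made here, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each tissue, the 12 libraries were fitted together with 4 group means, so that the groups shared 1 estimate of the spread. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM, and each comparison used edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested in that comparison. A gene was called when its adjusted p was under 0.05, with no limit on the fold change. All 24 libraries were fitted together with 8 group means for root against shoot in water and for the difference between the root and the shoot response at each time. Residual degrees of freedom were 8 in each tissue and 16 in the joint fit. Values in CPM are counts divided by the TMM-scaled library sizes of the tissue fit and brought to a common total. Those for root against shoot in water and in the plot of single libraries use the joint fit instead. The sign ± gives the standard deviation over the 3 libraries of a group. The fits took the libraries as unpaired.

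27 lists of genes with a known role were written before the data were examined, with 511 entries, of which 483 were in the table. Each list was tested against the other genes with camera (limma) on log2 CPM from voom, with the correlation between genes preset to 0.01 and Benjamini-Hochberg adjustment over the 27 lists and 3 times of a tissue. Beside each list, the genes called after adjustment over the list alone were counted, and camera was run again with a correlation estimated from the data. Lists shared members: the touch list shared 4 of its 6 members with other lists, and the singlet oxygen list 5 of 21.

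The genes named in the report were also chosen by a rule written in advance. For each tissue and PEG time, these are the 8 called genes that rose most and the 6 that fell most, among those with all 3 PEG libraries on the same side of all 3 water libraries and a higher group mean of at least 10 CPM. For each difference between tissues, for PEG 3 h against 1 h and for root against shoot in water, they are the 5 highest and the 5 lowest log2 fold changes among called genes, without the condition on sides for the differences. Up to 4 members per list and tissue with the lowest adjusted p were added, and LOX1 to LOX6, NCED3, P5CS1, PRODH1, RD29A, RD29B and BAP1 were always included. Genes were left out of the text for length. Any gene outside the rule is marked where it is named.

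Each fit was tested on simulated data with 200 changed genes drawn on the means, library sizes and spreads of these samples. The changed genes were drawn from those above a minimum mean CPM, so the rates do not cover the weakest genes. Fewer genes changed than were called in the real comparisons, so the cutoff after adjustment differs as well. Among 100 genes changed by a factor of 4, the root fits recovered 99%, 99% and 98% at 1, 2 and 3 h and the shoot fits 93%, 93% and 97%. Among 100 genes changed by a factor of 2, the root fits recovered 73%, 60% and 85% and the shoot fits 55%, 49% and 63%. These simulations tested 10716, 10705 and 10565 genes in root and 13577, 13512 and 13401 in shoot. The simulated difference at 3 h, over 15087 genes, recovered 73% of changes by a factor of 4 and 27% of changes by a factor of 2. A list raised by a factor of 2 in root at 3 h was called in 10 of 10 runs, with 0 calls of other lists. Genes were drawn independently in these runs, so they do not test the preset correlation between genes on which the list calls depend.

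Library totals ran from 343397 to 5495746 counts. A gene listed at 0 in a library was taken to allow up to 3 counts, which is 8.74 CPM in the smallest library and 0.55 CPM in the largest. Such floors, like all counting limits, cover counting error only. Comparisons of the 3 times share the same 3 water libraries, too few to divide, so overlaps of calls were set beside 20 simulations of unchanged groups against those libraries and beside the number for independent lists. HTSeq counts of genes with near-identical copies, such as extensins, are uncertain for single members.

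Alternatives written in advance were DESeq2's size factors in the same fit, no filter on low counts, DESeq2's Wald test, a log2 fold change of at least 1, 1 fit of all libraries, the replicate letter or seedling pool as a block, the digit of the library code as a term, each library left out in turn, and, for lists, camera with an estimated correlation and fry. Alternatives added after seeing the data left out the 2 shallowest libraries or a pair of shoot libraries, computed TMM within each tissue, or gave the list test a term for the library code digit. The samples of the PEG treatments with other compounds that the series title names were not analysed here.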

Results

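Transcripts were counted in roots and shoots of Arabidopsis thaliana seedlings (wild type Columbia-0, 7 days old) that had been held in 30% (w/v) polyethylene glycol (PEG) for 1, 2 or 3 h, or in water for 1 h. PEG of average molecular weight 8000 lowered the water potential of the solution to -2.0 MPa, which withdraws water from the tissue. The question was which transcripts change in each organ as osmotic stress lasts. The series title also names PEG with histidine, which quenches singlet oxygen, and PEG with SHAM, which inhibits lipoxygenases, and those samples were not analysed here. Genes of the singlet oxygen response and of lipoxygenases were followed because of that title. The 24 libraries formed 8 groups of 3 biological replicates, each a pool of 30 to 50 seedlings.

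Total counts per library ran from 1332586 (root PEG 1 h, replicate 3) to 5495746 in root, with a median of 4031935, and from 343397 (shoot PEG 2 h, replicate 2) to 4009409 in shoot, with a median of 3218775.5. A gene at 0 counts could hold up to 8.74 CPM in that smallest library and up to 2.25 CPM in the smallest root library. In the labelled roots, 47 of 47 nuclear photosynthesis genes were lower than in the labelled shoots in water (median log2 fold change -7.10), and 11 of 13 root tissue marker genes were higher (median 6.08). Nuclear photosynthesis genes held 21.6% to 26.7% of the counts in shoot libraries and 0.185% to 0.349% in root libraries. Replicates differed by more than counting error in every pair of libraries of a group, with chi-square per degree of freedom from 2.63 to 8.91.

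A pair of features of the design limits what the comparisons show. Water was sampled at 1 h alone, so at 2 and 3 h the effect of PEG cannot be told apart from that of the hours in solution. The digit of the library code in the sample descriptions also follows the groups in part. The codes run on in the order of the samples, and whether the digit marks a batch of libraries is not known. The root water libraries and root PEG 1 h replicate 1 carry digit 5 and the other root PEG libraries digit 6, whereas in shoots the water, 1 h and first 2 of the 2 h libraries carry 4 and the remaining ones 5.

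In roots, 2248 of 10941 genes tested were called at 1 h (1257 rose and 991 fell), 2744 at 2 h (1393 rose and 1351 fell) and 4440 at 3 h (2304 rose and 2136 fell). In shoots, 733 of 13769 genes were called at 1 h (585 rose and 148 fell), 1905 at 2 h (1127 rose and 778 fell) and 3578 at 3 h (1994 rose and 1584 fell). Whether more root genes rose or fell is not settled at any time. The share of root calls that rose was 55.9%, 50.8% and 51.9%, and over the alternatives it ran from 35.2% to 68.3% at 1 h, from 41.7% to 59.3% at 2 h and from 46.1% to 64.8% at 3 h. The majority in shoot at 3 h is not settled either, since 55.7% of those calls rose, while the authors' deposited values gave 1592 rises and 1938 falls. All these calls, like every gene's adjusted p in the report, come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested. With the library code digit as a term, the root counts were 629 (369 rose and 260 fell), 613 (353 rose and 260 fell) and 987 (455 rose and 532 fell), and 614, 577 and 962 of these genes were also called without the term. The shoot counts with that term were 961, 2096 and 2364. In root the term is nearly the same as the treatment and rests on PEG 1 h replicate 1, so few root calls can remain. In shoot all water and PEG 1 h libraries share 1 digit. Counts with the term therefore do not rank the tissues, while without it fewer genes were called in shoot than in root at each time. Single libraries weighed on the counts at 1 and 2 h: 1249 genes were called in root at 1 h without PEG 1 h replicate 2, and 397, 452 or 398 in shoot at 1 h without water replicate 1, water replicate 3 or PEG 1 h replicate 3. In shoot at 2 h, 918 genes were called without water replicate 1 and 857 without PEG 2 h replicate 1.

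**Figure D1:**
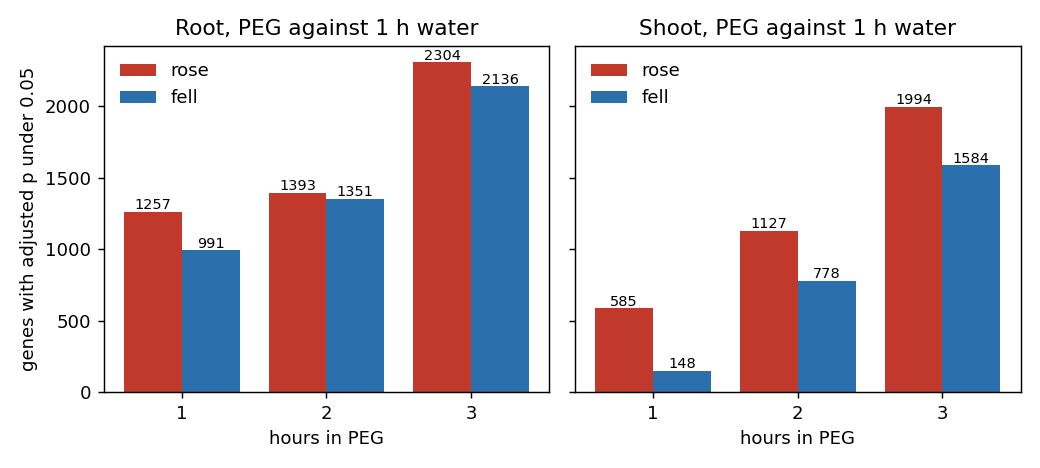
Number of genes that rose or fell in each comparison of PEG with water (adjusted p under 0.05, edgeR's quasi-likelihood test), for roots and shoots at 1, 2 and 3 h. Counts at 1 and 3 h were 2248 and 4440 in roots and 733 and 3578 in shoots.

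The comparison of root PEG at 1 h with water shows the first root response, at the time that has its own control. EXT12 (AT4G13390) encodes an extensin, a structural glycoprotein of the wall, and dropped from 145 ± 21.5 CPM to 10.9 ± 1.38 CPM (n = 3; log2 fold change -3.75, adjusted p = 7e-10). Of the 6 genes with the largest falls under the naming rule, 5 were extensins or extensin-like (EXT12, EXT6, EXT13, AT4G08400 and AT4G08410), and these are so alike in sequence that the share of each single member is uncertain. The sixth was HAK5 (AT4G13420), a potassium transporter of high affinity, which dropped from 47.3 ± 13.5 CPM to 4.15 ± 0.95 CPM (log2 fold change -3.57, adjusted p = 3.6e-08). Among the 8 genes with the largest rises under that rule were factors of the AP2/ERF family. ERF13 (AT2G44840) rose from 9.44 ± 1.52 CPM to 179.7 ± 6.83 CPM (log2 fold change 4.25, adjusted p = 0.00029) and ORA47 (AT1G74930) from 2.24 ± 0.107 CPM to 47 ± 14.1 CPM (log2 fold change 4.42, adjusted p = 0.00023). Of the 14 genes that the rule named here, 12 kept their call under every alternative.

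In roots at 2 h, HAI2 (AT1G07430), a protein phosphatase that acts on the signalling of abscisic acid (ABA), went from 0.609 ± 0.67 CPM in water to 19.4 ± 4.68 CPM (log2 fold change 5, adjusted p = 2.1e-06). MAPKKK18 (AT1G05100), an ABA-induced kinase, rose from 2.84 ± 0.855 CPM to 61.5 ± 20.4 CPM (4.44, adjusted p = 4.1e-06). RHS12 (AT3G10710), named for its expression in root hairs, dropped from 15.1 ± 1.75 CPM to 0.642 ± 0.335 CPM (log2 fold change -4.41, adjusted p = 7.4e-08). All 14 genes named at 2 h kept their call under every alternative. At 3 h, DREB2A (AT5G05410), a factor of the drought response, reached 90.4 ± 24.6 CPM from 2.29 ± 1.05 CPM in water (5.31, adjusted p = 7.9e-05). A pair of loci without a symbol also rose: AT2G01008 reached 67.2 ± 12.3 CPM (6.43, adjusted p = 6.9e-10) and AT3G06325 reached 85.3 ± 17 CPM (5.73, adjusted p = 1.5e-10). COBL9 (AT5G49270), needed for root hair growth, dropped from 15 ± 3.57 CPM to 0.711 ± 0.582 CPM (log2 fold change -4.26, adjusted p = 5.5e-06). It was the only one of the 14 named genes that lost its call under an alternative (adjusted p = 0.16 with the library code digit as a term).

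PEG at 3 h against 1 h asked what changed as the stress went on, between libraries of which 1, replicate 1 at 1 h, has another library code digit. In roots 609 genes rose and 939 fell, and 888 in total were called without PEG 3 h replicate 2. TSPO (AT2G47770), an ABA-induced membrane protein, rose from 1.99 ± 0.452 CPM to 18.7 ± 4.82 CPM (log2 fold change 3.18, adjusted p = 1.7e-05). PHI-1 (AT1G35140), a relative of the growth gene EXORDIUM, fell back from 282.5 ± 11.3 CPM to 56.8 ± 13.4 CPM (log2 fold change -2.32, adjusted p = 7.6e-06), against 54.3 ± 18.7 CPM in water. The split of this comparison depended on the fit, since 39.3% of the calls rose in the root fit and 79.5% in a fit of all 24 libraries.

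Calls at the 3 times overlapped in each tissue. In roots 688 genes rose and 755 fell at all 3 times, and in shoots 494 rose and 121 fell. Of the root calls at 1 h, 81% were called in the same direction at 3 h (969 rose and 853 fell, against 264.7 and 193.5 for independent lists), and of the shoot calls 92.9% (542 rose and 139 fell, against 84.7 and 17). Simulated unchanged groups against the same water libraries gave 0 shared calls, which says little, since genes of unchanged groups are rarely called at all. The covariance of log2 fold changes across genes, which are not independent replicates, was 0.626 between 1 and 3 h in root and 0.373 in shoot, against 0.058 and 0.054 in the simulations. Their correlation was 0.81 in root and 0.84 in shoot, against 0.46 and 0.52 in the simulations. Part of the overlap may come from the shared water libraries, which were too few to divide.

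Lists of genes with a known role were tested with camera (limma), two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 81 tests per tissue. Of these, 39 were called in root (27 up and 12 down) and 39 in shoot (30 up and 9 down). With a correlation estimated from the data, camera called 0 lists in either tissue after adjustment, while 13 root and 21 shoot tests had an unadjusted p under 0.05, and fry, which tests a list without comparing it with other genes, called 52 and 40. Every list call within a tissue therefore depends on the preset correlation, and the adjusted p with an estimated correlation is given beside it. Fry did not call 2 of the root lists and times that camera called, ABA metabolism and signalling genes at 1 h and ribosomal protein genes at 3 h. In shoot it did not call 6. These were LEA and ribosome biogenesis genes at 1 h, proline and sugar genes at 1 and 2 h, and ribosomal protein genes at 1 and 3 h.

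**Figure D2:**
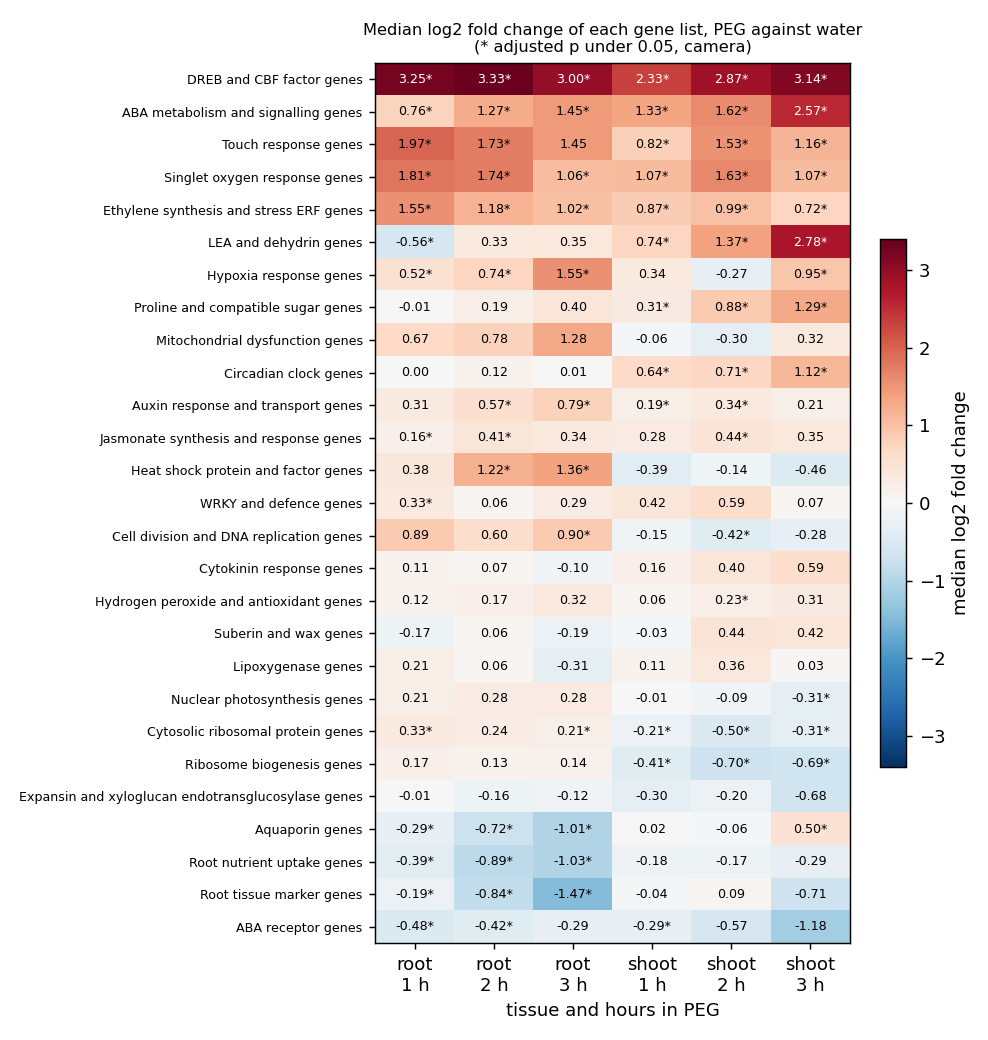
Median log2 fold change against water of 27 gene lists in root and shoot at 1, 2 and 3 h of PEG, with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. ABA, DREB, ethylene and singlet oxygen lists went up in both tissues, while nutrient uptake and root marker lists went down in root.

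ABA metabolism and signalling genes went up in roots. NCED3 (AT3G14440) encodes the enzyme that limits ABA synthesis and rose from 0.823 ± 0.255 CPM to 9.02 ± 0.89, 17.2 ± 5.83 and 29.6 ± 12 CPM at 1, 2 and 3 h (log2 fold change 5.11 at 3 h, adjusted p = 1.2e-07). That NCED3 call was kept with the library code digit as a term (adjusted p = 0.00045). RD26 (AT4G27410), a NAC factor of the ABA response, rose to 260 ± 39.4 CPM at 3 h from 30.8 ± 1.82 CPM (3.07, adjusted p = 1.1e-09). Of 26 members tested, 11 rose and 2 fell at 1 h, 19 rose and 1 fell at 2 h, and 19 rose at 3 h (12 and 4, 19 and 1, and 19 and 0 when adjusted over the list alone). The list medians were 0.76, 1.27 and 1.45 (camera adjusted p = 0.018, 6.2e-09 and 1.4e-08; adjusted p = 0.54, 0.27 and 0.27 with an estimated correlation), and the call of ABA metabolism and signalling genes at 1 h was lost without PEG 1 h replicate 1 (adjusted p = 0.1). ABA receptor genes went the other way. PYL6 (AT2G40330) dropped from 402.4 ± 39.6 CPM to 137.9 ± 18.7 CPM at 3 h (log2 fold change -1.54, adjusted p = 4.3e-07). Of 8 receptor genes, 3, 4 and 4 fell while 0, 0 and 2 rose (adjusted over the list alone, 4, 4 and 4 fell and 1, 0 and 2 rose). The receptor list was called down at 1 and 2 h (medians -0.48 and -0.42, adjusted p = 0.04 and 0.023; adjusted p = 0.36 and 0.35 with an estimated correlation). The call of ABA receptor genes at 1 h was lost without PEG 1 h replicate 1 (adjusted p = 0.055) or water replicate 3 (adjusted p = 0.086).

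Lists of DREB and ethylene factors were called up in roots at each time. Of 8 DREB and CBF genes, 6 rose at each time and 1 fell at 3 h, the same counts as when adjusted over the list alone. Medians were 3.25, 3.33 and 3.00 (adjusted p = 6.9e-05, 0.00012 and 0.0094; adjusted p = 0.22, 0.22 and 0.35 with an estimated correlation). CBF4 (AT5G51990), a drought-responsive member, went from 2.86 ± 0.864 CPM to 24.4 ± 5.58 CPM at 1 h (3.11, adjusted p = 3.2e-07). Of 17 genes of ethylene synthesis and stress ERF factors, 13, 13 and 10 rose and 0, 0 and 1 fell (adjusted over the list alone, 13, 13 and 11 rose and 0, 1 and 1 fell). Medians were 1.55, 1.18 and 1.02 (adjusted p = 4.6e-10, 1.2e-05 and 0.001; adjusted p = 0.18, 0.27 and 0.35 with an estimated correlation). ERF1A (AT4G17500) rose from 146.6 ± 18.8 CPM to 485.5 ± 61.2 CPM at 1 h (1.72, adjusted p = 1.2e-07). Touch response genes, 4 of whose 6 members are shared with other lists, rose in 5, 4 and 4 cases and fell in 1 at 3 h (5, 5 and 4 rose when adjusted over the list alone). Touch response genes were called up at 1 and 2 h (medians 1.97 and 1.73, adjusted p = 0.001 and 0.0089; adjusted p = 0.18 and 0.22 with an estimated correlation).

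Singlet oxygen response genes, which respond to that form of reactive oxygen, were called up in roots at each time. Of 17 tested, 15, 14 and 10 rose and 1 fell at 3 h (16, 15 and 11 rose when adjusted over the list alone). Medians were 1.81, 1.74 and 1.06 (adjusted p = 1.5e-14, 1.2e-09 and 0.00068; adjusted p = 0.22, 0.27 and 0.41 with an estimated correlation). SZF1 (AT3G55980), a zinc finger gene, went from 43 ± 8.78 CPM to 294 ± 32.7 CPM at 1 h and 113.2 ± 34.4 CPM at 3 h (log2 fold change 2.77 at 1 h, adjusted p = 6.3e-07). WRKY33 (AT2G38470), a defence factor, rose from 30.2 ± 6.25 CPM to 148.2 ± 15.5 CPM at 1 h (2.31, adjusted p = 1.9e-08). BAP1 (AT3G61190), a membrane protein gene often read as a singlet oxygen reporter, went from 101.4 ± 21 CPM to 355.1 ± 26 CPM at 1 h (1.81, adjusted p = 0.0083), a call lost with the library code digit as a term (1.84, adjusted p = 0.083). BAP1 was not called at 2 h (1.1, adjusted p = 0.054), except with DESeq2's Wald test or the replicate block (adjusted p = 0.025 and 0.034), nor at 3 h (0.39, adjusted p = 0.43), except without PEG 3 h replicate 3 (0.75, adjusted p = 0.0028).

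Lipoxygenases start the synthesis of jasmonate and other oxylipins, and the list of 5 tested in root was not called (medians 0.21, 0.06 and -0.31; adjusted p = 0.45, 0.75 and 0.4). Of these lipoxygenases 2 rose and 1 fell at 1 h, 1 rose at 2 h and 0 were called at 3 h. LOX3 (AT1G17420) rose from 3.31 ± 1.09 CPM to 10.3 ± 2.27 CPM at 1 h (1.67, adjusted p = 0.012), and LOX4 (AT1G72520) from 6.25 ± 3.09 CPM to 26.8 ± 3.6 CPM (2.1, adjusted p = 0.016). LOX1 (AT1G55020) fell from 72.5 ± 4.8 CPM to 49.2 ± 11.5 CPM (log2 fold change -0.54, adjusted p = 0.03). With the library code digit as a term these calls were lost (adjusted p = 0.11, 0.21 and 0.69). They were also lost without PEG 1 h replicate 2 (adjusted p = 0.067 for LOX3, 0.077 for LOX4 and 0.13 for LOX1), without water replicate 3 for LOX3 and LOX4 (adjusted p = 0.052 and 0.051), without water replicate 2 for LOX3 (adjusted p = 0.06), and without water replicate 1 or PEG 1 h replicate 3 for LOX1 (adjusted p = 0.074 and 0.086). LOX6 was not called at any time, and LOX5 only at 3 h without PEG 3 h replicate 1 (log2 fold change -0.67, adjusted p = 0.0092). The list of jasmonate genes was called up at 1 and 2 h (medians 0.16 and 0.41, camera adjusted p = 0.044 and 0.04, and adjusted p = 0.47 at both with an estimated correlation). Of 18 members, 7, 8 and 7 rose and 1, 1 and 4 fell (7, 8 and 8 and 1, 2 and 4 when adjusted over the list alone). Without water replicate 3 the calls of jasmonate synthesis and response genes were lost (adjusted p = 0.24 and 0.23), as they were without PEG 2 h replicate 1 (adjusted p = 0.057 and 0.08) and, at 1 h, without PEG 1 h replicate 1 (adjusted p = 0.09) or with the replicate block (adjusted p = 0.066). AOS (AT5G42650), which follows lipoxygenase in that synthesis, rose from 118.5 ± 17.2 CPM to 339.6 ± 16.5 CPM at 1 h (1.52, adjusted p = 3.5e-07). CYP94C1 (AT2G27690), which breaks down active jasmonate, fell from 32.4 ± 11.5 CPM to 6.83 ± 1.28 CPM at 3 h (log2 fold change -2.25, adjusted p = 1.6e-06).

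The lists of aquaporins, nutrient uptake genes and root tissue markers were called down in roots at each time. Of 19 aquaporin genes, which encode water channels, 7, 11 and 11 fell and 1, 1 and 3 rose (adjusted over the list alone, 9, 11 and 11 fell and 2, 3 and 4 rose). Medians were -0.29, -0.72 and -1.01 (adjusted p = 0.0092, 0.00012 and 0.00047; adjusted p = 0.42, 0.35 and 0.35 with an estimated correlation). PIP2;4 (AT5G60660) of the plasma membrane dropped from 211.4 ± 21.3 CPM to 51.5 ± 5.58 CPM at 3 h (log2 fold change -2.03, adjusted p = 7.1e-09). Of 16 nutrient uptake genes, 7, 11 and 11 fell and 1, 0 and 2 rose (9, 11 and 11 fell when adjusted over the list alone). Medians were -0.39, -0.89 and -1.03 (adjusted p = 0.00031, 3.6e-06 and 6.1e-06; adjusted p = 0.22, 0.18 and 0.18 with an estimated correlation). PHT1;1 (AT5G43350), a phosphate transporter, dropped from 1060 ± 68.6 CPM to 294 ± 32.5 CPM at 3 h (log2 fold change -1.85, adjusted p = 9.6e-09). Of 12 root tissue markers, 3, 9 and 8 fell and 1 rose at 3 h (4, 9 and 9 fell when adjusted over the list alone). Medians were -0.19, -0.84 and -1.47 (adjusted p = 0.03, 1.4e-05 and 1.8e-05; adjusted p = 0.35, 0.18 and 0.18 with an estimated correlation). CASP1 (AT2G36100), which places the Casparian strip of the endodermis, dropped from 432.3 ± 13.3 CPM to 123.8 ± 12.9 CPM at 3 h (log2 fold change -1.80, adjusted p = 2.1e-09).

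In roots heat shock genes, which encode chaperones and their factors, rose in 3, 9 and 11 of 16 cases and fell in 1 at 1 h (3, 9 and 12 rose when adjusted over the list alone). As a list they were called up at 2 and 3 h (medians 1.22 and 1.36, adjusted p = 0.00047 and 0.00069; adjusted p = 0.36 at both with an estimated correlation). HSFA3 (AT5G03720), a heat shock factor that DREB2A activates, went from 2.99 ± 0.0611 CPM to 18.8 ± 1.91 CPM at 2 h (2.64, adjusted p = 1.1e-06). Of 13 hypoxia genes, 1, 4 and 9 rose (1, 6 and 10 when adjusted over the list alone, with 0, 1 and 1 falling). Medians were 0.52, 0.74 and 1.55 (adjusted p = 0.017, 0.017 and 0.00068; adjusted p = 0.36, 0.35 and 0.27 with an estimated correlation). The hypoxia response genes lost their call without water replicate 3 (adjusted p = 0.078 at 1 h and 0.065 at 2 h) and, at 1 h, without PEG 1 h replicate 1 (adjusted p = 0.077). The list of LEA and dehydrin genes, whose proteins protect drying cells, was called down at 1 h (median -0.56, camera adjusted p = 0.0012, and adjusted p = 0.36 with an estimated correlation). Of their 12 members, 0, 4 and 4 rose and 5, 1 and 3 fell (0, 4 and 4 and 7, 2 and 4 when adjusted over the list alone). With the library code digit as a term that call was lost (adjusted p = 0.075) and the list was called up at 2 and 3 h (adjusted p = 0.0014 and 0.008). LEA4-5 (AT5G06760) rose from 12.4 ± 2.14 CPM to 90.2 ± 34 CPM at 3 h (2.86, adjusted p = 0.00022). RD29A (AT5G52310), a widely used drought marker, stood at 671.3 ± 56.7 CPM in water and was not called in root at 1 h (log2 fold change -1.03, adjusted p = 0.1), 2 h (0.66, adjusted p = 0.26) or 3 h (0.73, adjusted p = 0.16). RD29A was called down at 1 h without PEG 1 h replicate 1 (log2 fold change -1.63, adjusted p = 0.0053) and by DESeq2's Wald test (log2 fold change -1.08, adjusted p = 0.04). It was called up at 2 and 3 h with the code digit as a term (1.89 and 1.96, adjusted p = 0.047 and 0.029). In root that term is set by how PEG 1 h replicate 1 differs from replicates 2 and 3. The RD29A and LEA results with the term and the RD29A call without that replicate thus turn on the same library and are not separate checks. P5CS1 (AT2G39800), which makes the protectant proline, rose from 39 ± 2.55 CPM to 104.5 ± 33.7 CPM at 3 h (1.42, adjusted p = 5.5e-05), and PRODH1, which degrades it, was not called in either tissue.

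In roots, of 23 ribosomal protein genes, 5, 3 and 10 rose (8, 1 and 10 when adjusted over the list alone). Ribosomal protein genes were called up at 1 and 3 h (medians 0.33 and 0.21, adjusted p = 4.6e-05 and 0.02; adjusted p = 0.36 and 0.55 with an estimated correlation). Both calls of cytosolic ribosomal protein genes were lost with the code digit as a term (adjusted p = 0.18, and 0.47 with the direction down), and the one at 3 h also without PEG 3 h replicate 1 (adjusted p = 0.057) or water replicate 1 (adjusted p = 0.052). Cell division genes were called up at 3 h (5 of 10 rose, 6 when adjusted over the list alone; median 0.90, adjusted p = 0.023; adjusted p = 0.27 with an estimated correlation), and this was lost with the digit (adjusted p = 0.25). Auxin genes were called up at 2 and 3 h (8 and 9 of 16 rose and 1 and 2 fell, the same counts as over the list alone; medians 0.57 and 0.79, adjusted p = 0.012 and 0.042; adjusted p = 0.35 at both with an estimated correlation). At 3 h the call of auxin response and transport genes was lost without PEG 3 h replicate 1, water replicate 2 or water replicate 3 (adjusted p = 0.071, 0.072 and 0.055). PIN3 (AT1G70940), an auxin efflux carrier, rose from 19.8 ± 3.64 CPM to 62.7 ± 1.39 CPM at 3 h (1.67, adjusted p = 1.5e-05). WRKY and defence genes were called up at 1 h (4 of 14 rose, 6 when adjusted over the list alone; median 0.33, adjusted p = 0.0089; adjusted p = 0.35 with an estimated correlation).

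The remaining 9 lists were not called in root at any time, though some of their members changed. Wall-loosening genes split, since 5 of 23 expansin and xyloglucan endotransglucosylase genes rose and 10 fell at 3 h (6 and 10 when adjusted over the list alone). XTH14 (AT4G25820), active in root hairs, dropped from 297.2 ± 19.9 CPM to 44.4 ± 1.61 CPM at 1 h (log2 fold change -2.75, adjusted p = 2.3e-10). Of 15 hydrogen peroxide and antioxidant genes, 5 rose and 3 fell at 3 h (6 and 4 when adjusted over the list alone), among them FER1 (AT5G01600), an iron store, which rose from 398 ± 36.3 CPM to 1088 ± 78.4 CPM (1.45, adjusted p = 2e-07). Of 13 proline and sugar genes, 6 rose and 2 fell at 3 h (6 and 3 when adjusted over the list alone; median 0.40, adjusted p = 0.13). That list was called with the code digit as a term (adjusted p = 0.0015), which in root rests on PEG 1 h replicate 1. At 3 h, 2 of 7 mitochondrial dysfunction genes rose, 3 of 43 photosynthesis genes (0 when adjusted over the list alone), 1 of 9 ribosome biogenesis genes, 1 of 4 cytokinin genes with 1 falling, 4 of 15 clock genes with 5 falling, and 2 of 12 suberin and wax genes with 2 falling. But for photosynthesis genes these counts were the same when adjusted over the list alone. The signs of median, mean and test differed for clock genes (medians 0.00 and 0.01, means 0.09 and 0.30, direction down at 1 and 3 h), for cytokinin genes at 3 h (median -0.10, mean -0.02, direction up) and for suberin genes at 3 h (median -0.19, mean 0.03).

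Shoot PEG at 1 h against water gave more rises than falls. CBF3 (AT4G25480), a cold and drought factor, rose from 4.28 ± 0.539 CPM to 78.4 ± 6.51 CPM (log2 fold change 4.18, adjusted p = 1.4e-11). ATAF1 (AT1G01720), a NAC factor, rose from 74.5 ± 2.39 CPM to 724.7 ± 380 CPM (3.28, adjusted p = 9.7e-06). EXO (AT4G08950), a gene of cell expansion, dropped from 381.3 ± 94.8 CPM to 78.5 ± 15.1 CPM (log2 fold change -2.28, adjusted p = 1.1e-06). AGP17 (AT2G23130), an arabinogalactan protein, dropped from 101.1 ± 11.3 CPM to 26.1 ± 3.69 CPM (log2 fold change -1.95, adjusted p = 9.6e-07). Of the 14 genes named here, 12 kept their call under every alternative. ERF53 (AT2G20880), a drought-induced factor, went from 4.04 ± 0.77 CPM to 55.2 ± 50.2 CPM (3.75, adjusted p = 0.026), and its call was lost without any 1 of the water libraries (adjusted p = 0.12, 0.09 and 0.097) and with the replicate block (adjusted p = 0.065).

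In shoots at 2 h DREB2A stood at 183.8 ± 9.74 CPM against 12.6 ± 1.51 CPM in water (3.88, adjusted p = 1.6e-07), and AGP17 at 16.3 ± 6.69 CPM (log2 fold change -2.49, adjusted p = 1.5e-07). Of the 14 genes named at 2 h, 10 kept their call under every alternative, and COR15B, HAI2, PUB19 and RL3 did not. At 3 h ERF53 reached 265.6 ± 3.08 CPM (6.02, adjusted p = 0.00051). PUB19 (AT1G60190), a ubiquitin ligase of the ABA response, reached 278.3 ± 31.8 CPM against 4.87 ± 2.3 CPM in water (5.82, adjusted p = 0.00078), and COR15B (AT2G42530), a chloroplast protein that protects membranes, 154.8 ± 39.4 CPM against 3 ± 0.516 CPM (5.68, adjusted p = 0.0045). FLA9 (AT1G03870), a fasciclin-like cell wall protein, dropped from 429.8 ± 7.28 CPM to 38.7 ± 4.11 CPM (log2 fold change -3.47, adjusted p = 0.001). Of the 14 genes named at 3 h, 13 kept their call under every alternative.

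PEG at 3 h against 1 h in shoots gave 283 genes that rose and 224 that fell, and this count and its split rested on single libraries. All PEG 1 h libraries of shoots carry code digit 4 and all PEG 3 h libraries digit 5, so the hours and the code cannot be told apart here. With the digit as a term 747 genes were called, of which 251 were among the 507 called without it. Without PEG 1 h replicate 1, 2 or 3, 69, 81 or 1057 genes were called, and without PEG 3 h replicate 1, 2 or 3, 205, 109 or 254. GOLS2 (AT1G56600), which starts the synthesis of raffinose sugars, rose from 2.23 ± 1.43 CPM to 15.4 ± 6.77 CPM (2.81, adjusted p = 0.0016). IPT3 (AT3G63110), a cytokinin synthesis gene, fell from 23.49 ± 10.4 CPM to 6.01 ± 2.17 CPM (log2 fold change -1.95, adjusted p = 0.0065), and this call was lost without PEG 3 h replicate 2 (adjusted p = 0.054). Of the 10 genes named, 4 kept their call under every alternative.

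In shoots NCED3 rose from 1.71 ± 0.365 CPM to 58.6 ± 2.65 CPM at 3 h (5.07, adjusted p = 2e-05), and PP2CA (AT3G11410), a phosphatase of the ABA pathway, from 21.3 ± 3.5 CPM to 247.7 ± 19.7 CPM (3.54, adjusted p = 7.7e-07). Of 28 ABA metabolism and signalling genes, 8, 15 and 23 rose (17, 20 and 25 when adjusted over the list alone). Medians were 1.33, 1.62 and 2.57 (adjusted p = 8.7e-11, 9.6e-12 and 1.4e-17; adjusted p = 0.21, 0.19 and 0.17 with an estimated correlation). PYL6 dropped from 94.5 ± 6.4 CPM to 12.5 ± 2.88 CPM at 3 h (log2 fold change -2.92, adjusted p = 2.9e-07). Of 9 receptor genes 4, 4 and 5 fell and 0, 3 and 3 rose (4, 5 and 5 fell and 3 rose at each time when adjusted over the list alone). Their list was called down at 1 h (median -0.29, adjusted p = 0.022; adjusted p = 0.17 with an estimated correlation). All 14 LEA and dehydrin genes rose at 3 h, after 0 at 1 h and 9 at 2 h (5, 11 and 14 when adjusted over the list alone). Medians were 0.74, 1.37 and 2.78 (adjusted p = 0.0011, 7.6e-09 and 8.1e-13; adjusted p = 0.48, 0.19 and 0.17 with an estimated correlation). Without PEG 1 h replicate 3 the call of LEA and dehydrin genes at 1 h was lost (adjusted p = 0.18). COR47 (AT1G20440), a dehydrin, rose from 1023 ± 102 CPM to 3280 ± 306 CPM at 3 h (1.68, adjusted p = 0.00018), and RD29A from 221.8 ± 32.2 CPM to 2472 ± 182 CPM (3.48, adjusted p = 0.0052). Of 14 proline and sugar genes, 2, 5 and 8 rose (2, 6 and 9 when adjusted over the list alone). Medians were 0.31, 0.88 and 1.29 (adjusted p = 0.043, 0.0024 and 1.7e-05; adjusted p = 0.59, 0.38 and 0.25 with an estimated correlation). At 1 h the call of proline and compatible sugar genes was lost without PEG 1 h replicate 3, water replicate 1 or water replicate 3 (adjusted p = 0.27, 0.099 and 0.075) and with the replicate block (adjusted p = 0.058). P5CS1 rose from 8.66 ± 0.714 CPM to 114 ± 4.63 CPM at 3 h (3.71, adjusted p = 0.0095).

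The DREB, ethylene, singlet oxygen and touch lists were called up in shoots at each time. Of 8 DREB and CBF genes, 6 rose and 1 fell at each time, the same counts as when adjusted over the list alone. Medians were 2.33, 2.87 and 3.14 (adjusted p = 6.8e-08, 6.8e-08 and 4.8e-05; adjusted p = 0.1, 0.1 and 0.17 with an estimated correlation). Of 19 ethylene and ERF genes, 10, 12 and 10 rose and 0, 0 and 3 fell (11, 12 and 10 and 1, 1 and 3 when adjusted over the list alone). Medians were 0.87, 0.99 and 0.72 (adjusted p = 7.6e-09, 3.9e-09 and 0.0016; adjusted p = 0.083, 0.083 and 0.19 with an estimated correlation). ACS6 (AT4G11280), an enzyme of ethylene synthesis, rose from 15.5 ± 4.35 CPM to 81.9 ± 6.6 CPM at 2 h (2.4, adjusted p = 1.2e-07). Of 19 singlet oxygen genes, 11, 16 and 13 rose (14, 16 and 14 when adjusted over the list alone). Medians were 1.07, 1.63 and 1.07 (adjusted p = 1.4e-17, 1.4e-17 and 2.7e-08; adjusted p = 0.083, 0.083 and 0.17 with an estimated correlation). SZF2 (AT2G40140) rose from 62.2 ± 9.61 CPM to 307.9 ± 13.4 CPM at 3 h (2.3, adjusted p = 4.7e-09), while BAP1 was called at 2 h alone (0.76, adjusted p = 0.021). That BAP1 call was lost with the code digit as a term (adjusted p = 0.14) and without water replicate 1, water replicate 3 or PEG 2 h replicate 3 (adjusted p = 0.13, 0.071 and 0.14). Touch genes rose in 2, 3 and 3 of 6 cases and fell in 1 at 3 h (3, 5 and 3 rose when adjusted over the list alone; medians 0.82, 1.53 and 1.16, adjusted p = 0.0031, 3.9e-05 and 0.031; adjusted p = 0.25, 0.17 and 0.38 with an estimated correlation). At 3 h the call of touch response genes was lost with the code digit as a term (adjusted p = 0.37) and without water replicate 1 or PEG 3 h replicate 2 (adjusted p = 0.063 and 0.051).

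LOX2 (AT3G45140), a plastid lipoxygenase, fell from 110.8 ± 2.86 CPM to 71.3 ± 4.76 CPM at 1 h (log2 fold change -0.64, adjusted p = 0.01) and 69.3 ± 10.7 CPM at 2 h (log2 fold change -0.72, adjusted p = 0.0038). LOX2 was not called at 3 h (log2 fold change -0.38, adjusted p = 0.058). The LOX2 call at 1 h was lost without PEG 1 h replicate 3 (adjusted p = 0.053), and LOX2 was called at 3 h with DESeq2's size factors, DESeq2's Wald test or without PEG 3 h replicate 3 (adjusted p = 0.04, 0.044 and 0.049). LOX4 rose from 14.1 ± 3.84 CPM to 24.4 ± 7.69 CPM at 2 h (0.92, adjusted p = 0.025). That LOX4 call was lost with the code digit as a term (adjusted p = 0.095) and without water replicate 1, water replicate 3, PEG 2 h replicate 1 or PEG 2 h replicate 3 (adjusted p = 0.053, 0.11, 0.086 and 0.096). The list of 5 lipoxygenases, of which 0, 1 and 0 rose and 1, 1 and 0 fell (the same counts as when adjusted over the list alone), was called at no time (adjusted p = 0.7, 0.76 and 0.91).

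**Figure D3:**
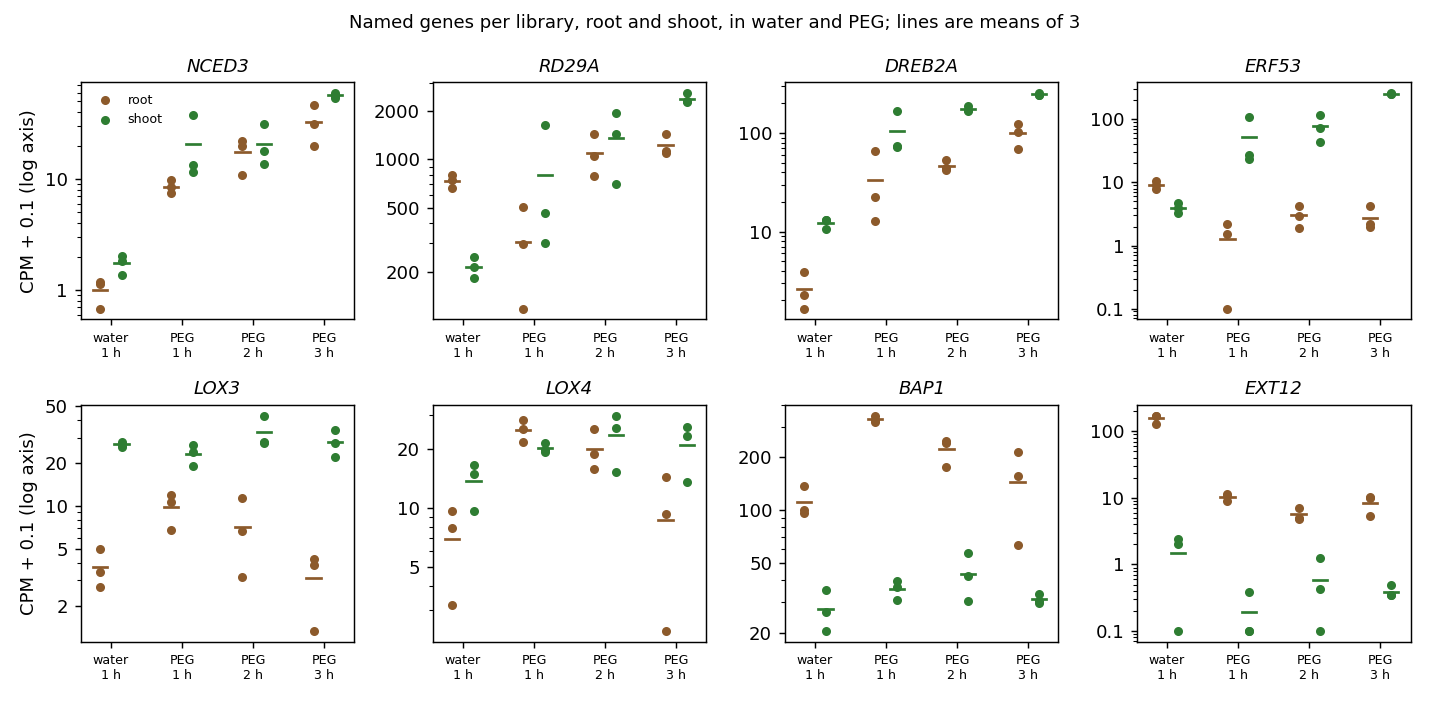
CPM plus 0.1 per library, scaled in the joint fit, on a log axis for NCED3, RD29A, DREB2A, ERF53, LOX3, LOX4, BAP1 and EXT12. Root and shoot libraries are shown in water and at 1, 2 and 3 h of PEG. Points are libraries and lines the mean of 3, and NCED3 rose in both tissues while ERF53 rose in shoots and fell in roots.

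The list of clock genes was called up in shoots at each time. FKF1 (AT1G68050), a blue light receptor of the photoperiod pathway, went from 14.1 ± 0.892 CPM to 63.8 ± 4.29, 82.5 ± 4.24 and 109.5 ± 14.3 CPM (log2 fold change 2.96 at 3 h, adjusted p = 1.5e-10). PRR5 (AT5G24470), an evening repressor, rose from 40.3 ± 7.86 CPM to 142.4 ± 13.1 CPM at 1 h (1.82, adjusted p = 4.6e-07). Of 17 clock genes, 5, 7 and 11 rose (8, 9 and 12 when adjusted over the list alone). Medians were 0.64, 0.71 and 1.12 (adjusted p = 6.5e-09, 7.2e-08 and 6.9e-08; adjusted p = 0.17 at each time with an estimated correlation).

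Lists of translation genes were called down in shoots at each time. Of 23 ribosomal protein genes, 0, 11 and 5 fell (0, 19 and 5 when adjusted over the list alone). Medians were -0.21, -0.50 and -0.31 (adjusted p = 0.00077, 3.4e-08 and 0.0014; adjusted p = 0.48, 0.25 and 0.49 with an estimated correlation). The call of cytosolic ribosomal protein genes at 1 h was lost without water replicate 1 (adjusted p = 0.061). By fry the calls of these genes at 1 and 3 h were lost (adjusted p = 0.23 and 0.095). Of 10 ribosome biogenesis genes, 1, 7 and 5 fell (2, 8 and 8 when adjusted over the list alone). Medians were -0.41, -0.70 and -0.69 (adjusted p = 0.00077, 2e-05 and 0.0012; adjusted p = 0.3, 0.2 and 0.32 with an estimated correlation). CBF5 (AT3G57150), which modifies ribosomal RNA, dropped from 157.2 ± 32.3 CPM to 58.6 ± 16.5 CPM at 2 h (log2 fold change -1.32, adjusted p = 5.7e-05). Of 47 photosynthesis genes, 0, 4 and 13 fell (0, 0 and 16 when adjusted over the list alone), and the list was called at 3 h (median -0.31, adjusted p = 1.6e-07; adjusted p = 0.38 with an estimated correlation). PSAH2 (AT1G52230) of photosystem I dropped from 789.2 ± 37.7 CPM to 432.5 ± 40.6 CPM at 3 h (log2 fold change -0.87, adjusted p = 0.00066). Cell division genes were called down at 2 h (1 of 17 fell, also when adjusted over the list alone; median -0.42, adjusted p = 0.017; adjusted p = 0.25 with an estimated correlation). This call of cell division and DNA replication genes was lost without PEG 2 h replicate 1 or water replicate 3 (adjusted p = 0.076 and 0.054).

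Aquaporin and hypoxia lists were called up in shoots at 3 h alone. Of 19 aquaporin genes, 11 rose and 2 fell then (11 and 3 when adjusted over the list alone; median 0.50, adjusted p = 0.022; adjusted p = 0.18 with an estimated correlation). PIP2;2 (AT2G37170) rose from 78.3 ± 8.88 CPM to 302.9 ± 17.5 CPM (1.95, adjusted p = 1.4e-06). Of 11 hypoxia genes, 6 rose (7 and 1 falling when adjusted over the list alone; median 0.95, adjusted p = 0.0028; adjusted p = 0.17 with an estimated correlation). ADH1 (AT1G77120), an alcohol dehydrogenase of fermentation, rose from 13.8 ± 2.03 CPM to 105.6 ± 31 CPM (2.94, adjusted p = 0.00017). Jasmonate genes were called up at 2 h (9 of 22 rose and 1 fell, 10 and 2 when adjusted over the list alone; median 0.44, adjusted p = 0.0021; adjusted p = 0.27 with an estimated correlation). Auxin genes were called up at 1 and 2 h (3 and 2 of 12 rose, 3 and 3 when adjusted over the list alone; medians 0.19 and 0.34, adjusted p = 0.028 and 0.043; adjusted p = 0.17 at both with an estimated correlation). Hydrogen peroxide genes were called up at 2 h (3 of 15 rose, also when adjusted over the list alone; median 0.23, adjusted p = 0.045; adjusted p = 0.17 with an estimated correlation). The auxin calls were lost under 9 alternatives at 1 h and 10 at 2 h, and the hydrogen peroxide call under 10.

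The other 8 lists besides lipoxygenases were not called in shoots. Heat shock genes split at 3 h, with 5 of 13 rising and 4 falling (5 and 5 when adjusted over the list alone). HSP90.1 (AT5G52640), an inducible chaperone, dropped from 32.1 ± 1.61 CPM to 7.1 ± 0.315 CPM (log2 fold change -2.17, adjusted p = 1.8e-07). At 3 h, 7 of 23 expansin and xyloglucan endotransglucosylase genes rose and 11 fell (7 and 13 when adjusted over the list alone), and 6 of 21 WRKY and defence genes rose and 5 fell (7 and 6 when adjusted over the list alone). Also at 3 h, 3 of 13 nutrient uptake genes rose and 4 fell, 3 of 9 mitochondrial dysfunction genes rose and 1 fell (2 fell when adjusted over the list alone), 2 of 10 suberin and wax genes rose and 1 fell, 1 of 8 root markers rose and 1 fell, and 1 of 4 cytokinin genes rose, otherwise with the same counts over the list alone. NIA2 (AT1G37130), a nitrate reductase, rose from 772.3 ± 72.9 CPM to 2161 ± 67.3 CPM (1.48, adjusted p = 1.6e-06). The signs of median, mean and test differed for heat shock genes (medians -0.39, -0.14 and -0.46, means 0.02, 0.10 and 0.01, direction down), for lipoxygenases at 1 and 3 h (medians 0.11 and 0.03, means 0.01 and 0.08, direction down), for aquaporins at 2 h (median -0.06, mean 0.09, direction down), for WRKY genes at 3 h (median 0.07, mean -0.05) and for suberin genes at 1 h (median -0.03, mean 0.05). They also differed for root tissue markers at 1 h (median -0.04, mean 0.11, direction down) and 2 h (median 0.09, mean -0.09, direction down).

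The difference between the root and the shoot response was tested directly over 15472 genes. The filters of the separate tissue fits kept 9455 genes in both. A called difference can therefore set the response of 1 tissue against very low counts in the other. It was called for 1220 genes at 1 h (421 with the higher log2 fold change in root and 799 in shoot), 1161 at 2 h (518 and 643) and 2599 at 3 h (1558 and 1041). Which tissue had more of the higher values is not settled at 1 and 2 h. At 1 h 34.5% of calls were higher in root with TMM and 56.2% with DESeq2's size factors, which moved the median difference by 0.153, and the share ran from 31.1% to 70.1% over the alternatives. At 2 h it was 44.6%, against 69% with no filter on low counts, and ran from 38.4% to 80.5%. Without root water replicate 1, 2 or 3, 684, 785 or 686 genes were called at 1 h, without root PEG 1 h replicate 2, 372, and without shoot water replicate 3 or shoot PEG 1 h replicate 3, 786 or 606. At 2 h 741 were called without shoot water replicate 1. ERF53 fell in root at 1 h, from 8.29 ± 1.19 CPM to 1.21 ± 1.1 CPM (log2 fold change -2.48, adjusted p = 0.0014), rose in shoot, and differed by -6.41, -6.04 and -7.76 at 1, 2 and 3 h (adjusted p = 0.0018, 0.001 and 2.7e-05). AT2G01008, which did not pass the filter in the shoot fit, differed by 6.59 at 3 h (adjusted p = 0.00032). That call was lost without shoot water replicate 1 (4.04, adjusted p = 0.14). RD29A differed by -3.14 at 1 h and -2.74 at 3 h (adjusted p = 0.02 and 0.021), LOX3 by 1.70 and LOX1 by -0.99 at 1 h (adjusted p = 0.02 and 0.047), whereas for NCED3 the difference was not called (-0.43, 0.52 and 0.04; adjusted p = 0.9, 0.85 and 0.99). Of the 10 genes named at each time, 1, 4 and 6 kept their call under every alternative.

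Across the 9455 genes tested in both tissues, 193, 310 and 614 rose in both at 1, 2 and 3 h (60.6, 104.1 and 318.4 for independent lists) and 24, 92 and 380 fell in both (9.5, 73.4 and 227.1). Spearman's correlation of the root and shoot log2 fold changes across genes was 0.04, 0.16 and 0.25, and genes are not independent replicates. At 1 h, 45 genes were called in opposite directions with the difference called, and EXO was one of them. It rose in root from 419.9 ± 83.4 CPM to 905.8 ± 67.3 CPM (1.11, adjusted p = 8.1e-05) and fell in shoot (log2 fold change -2.28), with a difference of 3.16 (adjusted p = 6.8e-09). PHI-1 also rose in root at 1 h (2.38, adjusted p = 2.1e-06) and fell in shoot (log2 fold change -0.98, adjusted p = 0.031), with a difference of 3.14 (adjusted p = 8.7e-06). Both were picked for this comparison after their values were seen.

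In water, 13205 of 15472 genes differed between root and shoot, 5848 higher in root and 7357 higher in shoot, and DESeq2's size factors moved the median log2 fold change by -0.238. AGP30 (AT2G33790), an arabinogalactan protein of roots, stood at 371.6 ± 21.7 CPM in root and 0.516 ± 0.488 CPM in shoot (9.40, adjusted p = 3.5e-22). LHCB5 (AT4G10340), a light-harvesting protein, stood at 0.643 ± 0.195 CPM in root and 4611 ± 239 CPM in shoot (log2 fold change -12.74, adjusted p = 1.5e-19). GER3, a germin-like protein gene, was listed at 367.1 ± 136 CPM in shoot and at 0 in root.

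At their adjusted p under 0.05, the authors' deposited table called 2081, 2463 and 4212 genes in root and 780, 1812 and 3530 in shoot at 1, 2 and 3 h. Of these, 1800, 2142 and 3693 in root and 605, 1526 and 2947 in shoot were also called by edgeR's quasi-likelihood test, all in the same direction. The majority went the other way in 3 of these comparisons, since by the authors' values 979 genes rose and 1484 fell in root at 2 h, 1940 rose and 2272 fell in root at 3 h, and 1592 rose and 1938 fell in shoot at 3 h. For PEG 3 h against 1 h the authors' values gave 1081 calls in root (417 rose and 664 fell) and 632 in shoot (305 rose and 327 fell), against 1548 and 507 by edgeR's test.

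On a score of the response, shoot libraries of 1 h and 2 h were not well parted, since replicate 3 of the 1 h group stood at 0.74 and replicate 3 of the 2 h group at 0.52.

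**Figure D4:**
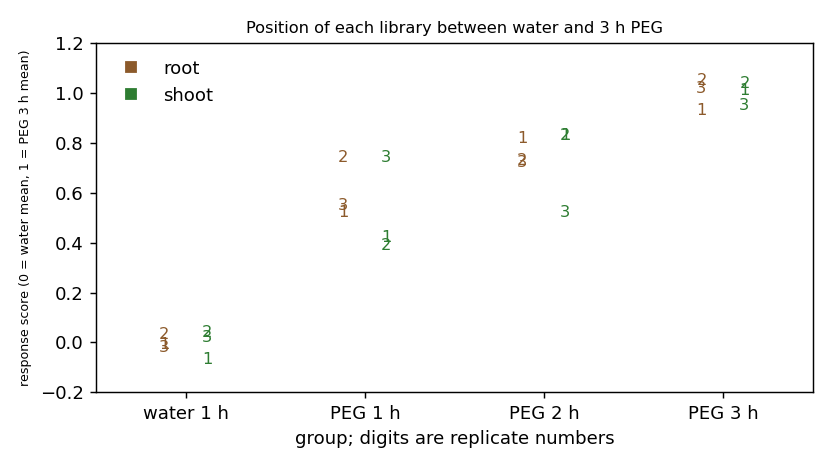
Response score of each library, which is the mean log2 CPM over genes called in a fit of the 3 water and 3 PEG 3 h libraries alone (4486 in root and 4119 in shoot), signed by their direction and scaled so that the mean of the water libraries is 0 and that of the 3 h libraries 1, for roots and shoots. Shoot PEG 1 h replicate 3 (0.74) lies above replicates 1 and 2 of its group (0.42 and 0.39), and shoot PEG 2 h replicate 3 (0.52) below replicates 1 and 2 of its own (0.83 each).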

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

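The tests of exchanged shoot labels, of the library code in shoots and of low depth in root were chosen after the result was seen, as were the tests of list differences between tissues, while the other splits, the exchange of seedling pools and the library code in root were planned in advance. The p-values of single genes measure the spread between biological replicates, pools of 30 to 50 seedlings. Those of camera set a list against the other genes and depend on the correlation between genes that is preset or estimated.

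Root and shoot responses to PEG differed by a test of the difference itself, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It called 1220 genes at 1 h, 1161 at 2 h and 2599 at 3 h. These include genes too weakly counted in 1 tissue to be tested there alone. At each time, 30 relabellings of PEG and water within each tissue were made, the real one included. Of these, 1 gave as many genes, which was the real one, and the highest of the others gave 623, 810 and 1752. The relabellings stand for no effect of PEG in either tissue. The exchange of PEG and water in shoot alone, with root kept, was left out. The counts therefore do not show whether chance could make equal responses of root and shoot look different. Of the genes called in both tissues, 45, 116 and 345 went in opposite directions with the difference called (17, 64 and 186 rose in root and fell in shoot, and 28, 52 and 159 the other way). These were all the opposite pairs of calls. Independent lists would give 54.3, 174.8 and 537.8 such pairs, more than were seen at each time. The labels name root and shoot as different tissues, and which property of the tissues sets the responses apart was not tested.

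The list test called 4 pairs of list and time in opposite directions in root and shoot, and camera with a preset correlation also called their difference, root minus shoot. For LEA and dehydrin genes it was -1.67 at 1 h (adjusted p = 0.00015; adjusted p = 0.43 with an estimated correlation). Cytosolic ribosomal protein genes differed by 0.36 at 1 h (adjusted p = 5e-06) and by 0.59 at 3 h (adjusted p = 1.8e-06), and both have an adjusted p = 0.33 with an estimated correlation. Aquaporin genes differed by -1.21 at 3 h (adjusted p = 1.1e-11), and this one held with an estimated correlation (adjusted p = 0.031). The separate aquaporin calls at 3 h were kept under every alternative but that correlation, and those of the other pairs were not. With a term for the library code digit the root calls were lost for LEA and dehydrin genes (adjusted p = 0.075) and for ribosomal protein genes at 1 and 3 h (adjusted p = 0.18 and 0.47). In shoot at 1 h the LEA and dehydrin call was lost without PEG 1 h replicate 3 (adjusted p = 0.18) and the ribosomal call without water replicate 1 (adjusted p = 0.061). The differences were not tested with the code digit as a term, so the library code stays open as a source of the LEA and ribosomal pairs. The scaling moves all 1 h differences alike, by 0.153 between TMM and DESeq2's size factors, which is less than each of the list differences at that time.

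Shoot PEG 1 h replicate 3 and shoot PEG 2 h replicate 3 lay apart from their groups. On the response score, the 1 h replicates stood at 0.42, 0.39 and 0.74 and the 2 h replicates at 0.83, 0.83 and 0.52. The library code is argued against for the 1 h replicate, because the 3 shoot PEG 1 h libraries carry 1 digit. It stays open for the 2 h replicate, which alone in its group carries the digit of the 3 h libraries. An exchange of the labels of these libraries was not decided. The 1 h replicate exceeded the 2 h replicate by 0.22, but neither reached the scores of replicates 1 and 2 of the other group. The rule for an exchange asked for both, and it was relaxed after the values were seen, so no conclusion is drawn from it. The pair of libraries cannot be told apart from replicates that vary. An exchange of whole seedling pools before roots and shoots were parted also stays open, because the root libraries of the same letter kept their order (a difference of -0.17), yet root scores at 1 h (0.52, 0.74 and 0.55) and 2 h (0.82, 0.73 and 0.72) overlap.

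The root response may also come in part from whatever the library code stands for, since PEG and water libraries mostly differ in it. Whether its digit marks a batch is not known. Root PEG 1 h replicate 1 shares the digit of the water libraries, and over 2449 genes called with the other 2 replicates its median signed log2 change was 0.63, against 1.07 in the other 2, or 59.3%. The genes were chosen and signed by the other 2, so a smaller change in the library left out follows in part from that choice, and the ratio decides nothing about the code. On the response score this replicate stood at 0.52 and replicate 3, with the other digit, at 0.55. With 1 library that shares the water digit, the code and the treatment cannot be told apart in root. In shoots all PEG 3 h libraries differ in digit from all water libraries. With the digit as a term 2364 genes were called there, of which 1841 were among the 3578 called without it. That term rests on PEG 2 h replicate 3, which lay apart from its group, so the code stays open there as well. The low depth of root PEG 1 h replicate 3 is argued against as the source of the 1 h count, because 2195 genes were called without it, against 2248 with it.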

How the results depend on the processing

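The alternatives that left out the shallowest libraries or a pair of shoot libraries, that computed TMM within each tissue, or that gave the list test a term for the library code were chosen after the data were seen. Of the counts of called genes and lists, 195 values under an alternative stayed within 1.5 times the main count and 36 did not. For the always-named genes, 555 values kept their sign and their side of the threshold, 34 lost a call, 16 gained one, and 25 uncalled values changed sign.

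A log2 fold change of at least 1 lowered the counts by construction, to 1126, 1210 and 2008 in root and 435, 1080 and 1930 in shoot at 1, 2 and 3 h, and to 514 in root and 293 in shoot for PEG 3 h against 1 h. The library code digit as a term left 629, 613 and 987 calls in root and 2364 in shoot at 3 h. In root this term is nearly the same as the treatment, so that the fit takes the effect of PEG from few libraries. Without shoot PEG 1 h and 2 h replicates 3, PEG 3 h against 1 h in shoot gave 1399 calls in place of 507. Camera with an estimated correlation called 0 lists in root and 0 in shoot in place of 39 each, with 13 and 21 tests at an unadjusted p under 0.05, and the cause was not tested.

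Leaving out each library in turn gave between 1249 and 2495 calls for root at 1 h, 397 and 679 for shoot at 1 h, 857 and 2135 for shoot at 2 h, 888 and 1426 for root PEG 3 h against 1 h, and 69 and 1057 for shoot PEG 3 h against 1 h. The differences between tissues ranged from 372 to 1272 at 1 h and from 741 to 1613 at 2 h. An arm with fewer libraries loses power by construction, and the lone or paired libraries are assumed to vary like the other groups. What makes single libraries weigh this much was not tested.

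No sign of pairing by the replicate letter was seen, though this does not show that root and shoot of 1 letter came from different pools. Deviations from group means correlated across genes by 0.029 on average over 18 pairs of root libraries with the same letter, by -0.048 over 18 pairs in shoot and by -0.006 over 12 pairs of root and shoot of 1 treatment, with 2 pairs over 0.1 in each. The replicate block left 325 calls for shoot PEG 3 h against 1 h, and it moved no other count of called genes or lists by over 1.5 times. With the seedling pool as the block, the differences between tissues were called for 866, 903 and 2131 genes at 1, 2 and 3 h, against 1220, 1161 and 2599.

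DESeq2's size factors and Wald test, no filter on low counts and 1 fit of all libraries kept the counts within 1.5 times, but moved several splits. Of the difference at 1 h, 34.5% was higher in root with TMM and 56.2% with size factors, and TMM within each tissue gave 622 higher and 532 lower of 1154. With no filter, 69% of the 2 h difference was higher in root, against 44.6%. The majority direction of the calls turned under at least 1 alternative in root against water at each time, in PEG 3 h against 1 h in both tissues and in the difference at 1 and 2 h. It turned under no alternative in shoot against water, in the difference at 3 h and in root against shoot in water, though the authors' deposited values turned it in shoot at 3 h (1592 rose and 1938 fell). In 1 fit of all libraries, 79.5% of root PEG 3 h against 1 h rose, against 39.3%, and 35.2% of root at 1 h, against 55.9%. The cause was not tested.

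Of the genes named for the size of their change, all kept their sign under every alternative in which they were tested. In root 12, 14 and 13 of 14 kept their call at 1, 2 and 3 h, and in shoot 12, 10 and 13 of 14. For PEG 3 h against 1 h it was 10 of 10 in root and 4 of 10 in shoot, for the differences 1, 4 and 6 of 10, and for root against shoot 9 of 10, the tenth not being tested by DESeq2. Of the list members named in root, 58, 81 and 91 were called at 1, 2 and 3 h and 37, 43 and 52 of them with the library code digit as a term. With it the log2 fold change of RPS6A at 2 h went from 0.68 to -0.18 and that of PCNA1 at 3 h from 1.98 to -0.46 (adjusted p = 0.81 and 0.89), and the other called members kept their sign. In shoot 47, 70 and 88 were called and 47, 68 and 74 with that term.

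Depth limits what can be seen of weak transcripts. The smallest library, shoot PEG 2 h replicate 2, held 343397 counts, where a gene at 0 has an upper limit of 8.74 CPM. In simulated data of these depths, changes by a factor of 2 were recovered for 49% to 63% of the changed genes in shoot. In root it was 60% to 85%. Those genes were drawn above a minimum mean CPM, so the rates do not cover the weakest transcripts. Genes that were not called are therefore not shown to be unchanged.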

Other observations

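Counts from organelle genes were a small part of each library. In shoot PEG 2 h replicate 2, the smallest library, chloroplast genes held 0.072% and mitochondrial genes 0.077% of the counts, against 0.487% to 0.69% and 0.368% to 0.477% in the other shoot libraries. In root PEG 1 h replicate 3, the smallest root library, mitochondrial genes held 3.96%, against 1.96% to 3.11% in the other root libraries. These values belong to no comparison and were not tested.

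EXO and PHI-1 belong to 1 family tied to growth, and both rose in root and fell in shoot at 1 h. In root the rise of PHI-1 had ended by 3 h (56.8 ± 13.4 CPM, against 54.3 ± 18.7 CPM in water), and EXO stood at 344.9 ± 70.6 CPM, against 419.9 ± 83.4 CPM in water (log2 fold change -0.28, adjusted p = 0.16, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In shoot both were lower than in water at 3 h (log2 fold change -3.07 for EXO and -1.66 for PHI-1, adjusted p = 1.7e-08 and 0.00022). The genes were chosen after their values were seen.

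Both tests of the clock genes in shoots were chosen after the result was seen. Clock transcripts change with the hour, so a rise under PEG may come from the hours in solution or from the stress. At 1 h, water and PEG libraries had the same time in solution. There the median log2 fold change of the 17 clock genes was 0.64. The list was called with adjusted p from 4.4e-10 to 0.0011 over 20 settings, camera with an estimated correlation aside (adjusted p = 0.17). The matched exposure, not this value, argues against the hours in solution at 1 h, since the rise was found in that same comparison. A difference in the hour of the day at harvest was not tested. At 3 h the median was 1.12, and no water library shares that hour, so PEG and the hour cannot be told apart there. The difference between tissues for this list was -1.07, -0.86 and -1.03 at 1, 2 and 3 h (adjusted p = 5e-06, 7.3e-06 and 6.9e-07; adjusted p = 0.14 at each with an estimated correlation). That the clock of shoots answers to osmotic stress within 1 h is thus a hypothesis, found and tested on the same data.

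For each comparison of 3 libraries with 3, the samples can be split in 10 ways, too few for a share under 0.05. The real split gave the highest count in each. It gave 2248, 2744 and 4440 calls in root and 733, 1905 and 3578 in shoot at 1, 2 and 3 h, and 13205 for root against shoot in water, while the highest other split gave 0 by edgeR's quasi-likelihood test. For PEG 3 h against 1 h the real split gave 1548 calls in root and 507 in shoot, and the highest other split 61 and 1.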
